A study of Arabidopsis thaliana and Cajanus cajan and Vigna radiata with 5 samples.

How the data were processed

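Small RNA was sequenced from 2-week-old leaves in 5 libraries, 1 per group. The groups were pigeon pea, mung bean, and Arabidopsis carrying a soybean MIR1510a transgene in 3 backgrounds: Col-0 wild type, urt1-1 and heso1-1. Per the labels, days had 16 h of light, pigeon pea was kept at 24 to 28 °C and the other plants at 22 to 23 °C, and the protocol names RNA purification with a plant RNA reagent. The library kit, the sequencer, the adapter trimmer and the filters are not given in the sources used here. TAIR10 is the only genome build listed, per the submitters' processing notes, with no role given.

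The deposited files hold, for each distinct read sequence, the raw count of reads with exactly that sequence, with no header, coordinates or miRNA names. Whole numbers from 1 upward that sum to different totals showed that these are counts and not normalized values. The totals were 12019258 reads for pigeon pea, 38854567 for mung bean, 39448550 for Col-0, 14638064 for urt1-1 and 27007977 for heso1-1. Reads were 18 to 34 nt long in 4 files and 15 to 49 nt in the mung bean file.

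The files differed in how they had been made. Those of pigeon pea, urt1-1 and heso1-1 were sorted by count, held reads with undetermined bases (0.0438%, 0.0160% and 0.0171% of reads) and held reads that still contained the first 12 bases of a common 3' adapter (0.581%, 0.134% and 0.157%). Those of mung bean and Col-0 were unsorted and held no undetermined bases, and the adapter was found in 0.000785% of mung bean reads and 0 Col-0 reads. Col-0 and the mutants therefore differed in file processing as well as in genotype, whereas urt1-1 and heso1-1 shared 1 format. No batch is given in the labels, and batch and genotype cannot be told apart in comparisons against Col-0.

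Reads were assigned to a miRNA when their first 18 bases equalled those of the mature sequence and they were at least 18 nt long. A list of 70 sequences was fixed before the data were examined: 33 conserved miRNAs, 21 Arabidopsis-lineage miRNAs, 10 legume miRNAs, 3 trans-acting siRNAs and 3 miR1510 forms, with overlapping lists of 14 miRNAs of 22 nt and 9 nutrient-responsive miRNAs. The sequences were written from general knowledge of the families. All 54 conserved and Arabidopsis sequences had an exact match in the TAIR10.1 reference, and 0 of the 10 legume sequences did. The miR1510-3p frame in that list started 1 base upstream of the form that the reads showed to be most frequent. The frame TGTTGTTTTACCTATTCCACC was therefore used for all main values after the data were seen, and the listed frame was kept as an alternative. miRNAs that share their first 18 bases (miR159a and miR159b, miR396a and miR396b, miR398a and miR398b) were counted together for levels. For 3' ends, their reads had to contain the whole mature sequence, and their values remain uncertain.

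A read was called monouridylated when it was the whole mature sequence plus 1 T. Endogenous miRNAs entered this measure with at least 100 anchored reads in each of the 3 Arabidopsis libraries, and miRNAs followed by a genomic T at any exact TAIR10.1 match were left out. This left 12 miRNAs. Levels were computed as reads per 1000000 reads of the file (RPM). A ratio of levels was computed with at least 100 anchored reads in the 2 libraries together, and a miRNA was called higher or lower at a ratio of 2-fold or more with an interval that excluded 1. The legume miR1510-3p search allowed up to 3 mismatches. Reads of the HESO1, URT1 and TAS loci were exact matches to the annotated span in TAIR10.1, on either strand. TAS siRNA sequences were compared when they had at least 300 reads over the 3 Arabidopsis libraries and at least 1 in each.

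With 1 library per group there is no replicate check. Shares carry Wilson 95% intervals, levels exact Poisson 95% intervals, ratios exact conditional 95% intervals and differences of shares Newcombe 95% intervals. Shares of 2 libraries were compared with a two-sided Fisher's exact test on reads, adjusted by the Benjamini-Hochberg method over the 12 miRNAs where miRNAs were tested. Such a test compares 2 libraries and not 2 genotypes. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Where a count was 0, the floor was 3 counts. Genes across the genome were not tested.

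Most named miRNAs followed a rule fixed before the data were examined: every miR1510 form, the 10 miRNAs with the most reads and the 10 with the largest ratio in each comparison of levels, the 10 with the largest difference in each comparison of 3' ends, and listed legume miRNAs and trans-acting siRNAs with at least 100 reads. Others were named outside that rule, for their role or because they reversed under an alternative. The alternatives, with their effect given in the closing section, changed the denominator, the anchor length, mismatches, rare sequences, the number of added T, the scaling, the read minimum and the 5' frame. On simulated data, 507 of 507 monouridylated reads among 2000 were recovered. With a simulated 4-fold lower share, the test recovered 96.5% of changed miRNAs for heso1-1 against Col-0, 92.6% for urt1-1 against Col-0 and 91.6% for heso1-1 against urt1-1. Unchanged miRNAs were called in 2.47%, 0.971% and 1.69% of cases. Every miRNA was simulated at a baseline share of 10%, above the real Col-0 median of 2.80%. Recovery at lower shares was not measured. The rule for levels recovered 100% of simulated 4-fold changes in all 4 comparisons and called 0 unchanged miRNAs. Of simulated changes of exactly 2-fold, the size at the threshold, it recovered 51.0%, 51.2%, 49.6% and 50.03%. All simulations drew counting error only. They give no rate of false calls for libraries that also vary in other ways. Phased siRNA targets, soybean and the legume genomes were not analysed here. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.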

Results

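Small RNA reads were collected from leaves of pigeon pea (Cajanus cajan), mung bean (a Vigna species of the same Phaseoleae tribe) and 3 Arabidopsis lines that express the soybean miR1510 precursor MIR1510a. miR1510 is a legume microRNA of 21 or 22 nt known to target genes of the NB-LRR disease resistance class. The series asks how its 22-nt form arises. HESO1 and URT1 are nucleotidyl transferases that add uridines to the 3' ends of RNA, and heso1-1 and urt1-1 are mutant alleles of their genes. Each group was 1 library without replicates, of 12019258 (pigeon pea) to 39448550 (Col-0) reads, so every difference below is between 2 libraries.

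Reads from the targeted genes were scarce. The URT1 locus (AT2G45620, chromosome 2, 18792864 to 18795904, plus strand, TAIR10.1) gave 32 reads in Col-0, 19 in heso1-1 and 1 in urt1-1. The urt1-1 level was 0.0842 of the Col-0 level (exact 95% interval 0.00207 to 0.504). The HESO1 locus (AT2G39740, chromosome 2, 16575752 to 16579120, plus strand) gave 19 reads in Col-0, 12 in urt1-1 and 4 in heso1-1, a ratio of heso1-1 to Col-0 of 0.308 (0.0761 to 0.925). Both loci thus had their lowest level in the mutant named for them. Small RNA reads do not measure the messenger RNA and cannot check a mutation.

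In the 3 Arabidopsis lines, the comparison of 3' ends asks which transferase adds the last base of miR1510. In Col-0, the main miR1510-3p forms were the 21-nt TGTTGTTTTACCTATTCCACC, with 1290 reads, and the same sequence plus T, with 2693 reads. Longer reads of the same strand, such as TGTTGTTTTACCTATTCCACCCAT, continued with C after the 21-nt form, so as far as the reads show, the T was not encoded next to it. The monouridylated share was 64.1% of 4202 anchored reads in Col-0 (Wilson 95% interval 62.6 to 65.5) and 65.5% of 351 in urt1-1 (60.4 to 70.3). In heso1-1 it was 2.69% of 483 (1.58 to 4.55), and the unextended 21-nt form made up 90.1% there, against 30.7% in Col-0 and 26.2% in urt1-1.

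The heso1-1 library was below Col-0, at 2.69% against 64.1% (difference -61.4 percentage points, 95% interval -63.2 to -59.0; two-sided Fisher's exact test on reads, p = 6.82e-170). It was also below urt1-1 (difference -62.8, -67.7 to -57.4; Fisher's exact p = 7.03e-96), and these 2 files had the same format. The urt1-1 library did not differ detectably from Col-0 (difference 1.44, -3.88 to 6.44; Fisher's exact p = 0.603). These tests compare libraries, not genotypes. In the 5' frame that had been listed before the data were examined, only 51, 2 and 11 reads were found in Col-0, urt1-1 and heso1-1. The Col-0 share there was 1.96% (Wilson 95% interval 0.347 to 10.3), far below the 64.1% of the main frame. The listed sequence also ends 1 base earlier, so the 2 shares count different 3' ends. In the mutants the reads were too few to compare the share.

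**Figure D1:**
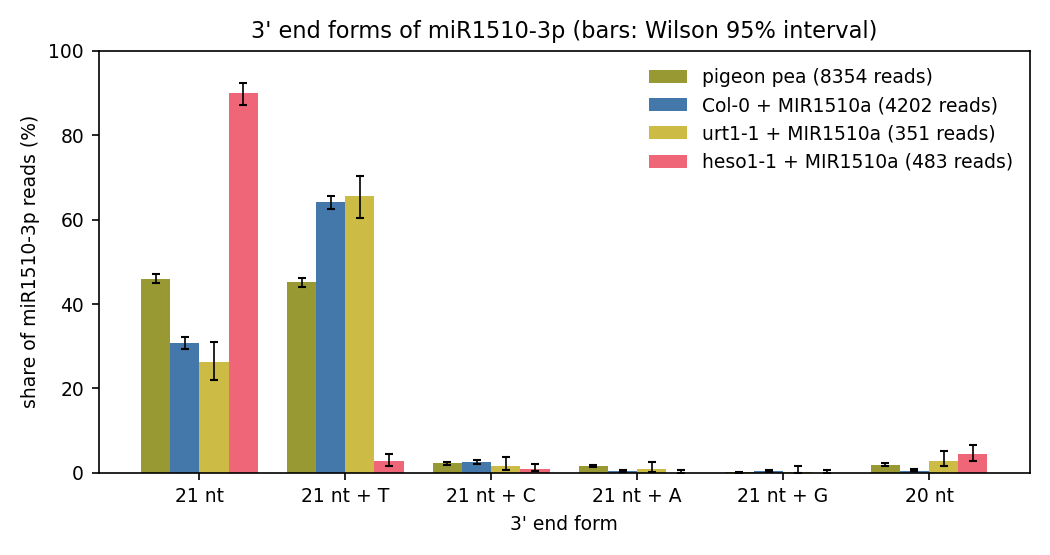
Share of anchored miR1510-3p reads (vertical axis, %) that ended in each 3' form (horizontal axis) in pigeon pea and the 3 Arabidopsis libraries, 1 library each, with Wilson 95% intervals as error bars. The form with 1 added T was at 64.1% in Col-0 and 65.5% in urt1-1 but at 2.69% in heso1-1.

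Added bases other than T were rare on miR1510-3p. The form plus C, the encoded base, was at 2.48% in Col-0, 1.71% in urt1-1 and 0.828% in heso1-1, and the form plus A at 0.476%, 0.855% and 0 of 483 reads, which allows up to 0.789% (Wilson upper bound). A second 5' start, 2 bases downstream, gave the 22-nt form TTGTTTTACCTATTCCACCCAT with 798 reads in Col-0, 69 in urt1-1 and 165 in heso1-1. Its reads carried 1 more T in 7.30% of 1178 in Col-0, 2.13% of 94 in urt1-1 and 1.70% of 235 in heso1-1. The base encoded after this form was not known, so an added T cannot be separated from an encoded one here. On this frame the mutants did not differ detectably from each other (Fisher's exact p = 1). The opposite strand, miR1510-5p (AGGGATAGGTAAAACAATGAC), carried 1 more T in 6.57% of 22551 reads in Col-0 (6.26 to 6.90), 3.94% of 7134 in urt1-1 (3.51 to 4.42) and 1.24% of 13490 in heso1-1 (1.06 to 1.44). The listed 5p sequence, AGGGATAGGTAAAACAATGACT, has that T, so an added T cannot be separated from an encoded one on this strand.

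miR1510-3p was found at 107 reads per 1000000 reads (RPM) in Col-0 (exact Poisson 95% interval 103 to 109.8), 24.0 in urt1-1 (21.5 to 26.6) and 17.9 in heso1-1 (16.3 to 19.6). In this frame of the 21-nt form, the 2 mutant libraries were thus 4.44-fold (3.98 to 4.97) and 5.96-fold (5.42 to 6.56) below Col-0. Such drops were not particular to miR1510-3p. Of 36 endogenous miRNAs, 15 in urt1-1 and 20 in heso1-1 were at least 2-fold below Col-0. The SD of the log2 ratio over the 36 was 2.86 and 2.69. The frame 2 bases downstream was at 29.9 RPM in Col-0, 6.42 in urt1-1 and 8.70 in heso1-1, so heso1-1 was the higher mutant there. The 5p strand of the same precursor was at 572, 487 and 499 RPM, a much smaller spread. The sum of conserved miRNAs as denominator kept Col-0 the highest of the 3 lines but gave heso1-1 a higher value than urt1-1.

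In pigeon pea, the same 2 forms of miR1510-3p dominated. Of 8354 anchored reads, 46.0% were the 21-nt form (Wilson 95% interval 44.9 to 47.0) and 45.1% that form plus T (44.1 to 46.2), while 2.24% carried C and 1.59% A. Among all 8817 miR1510-3p-like reads, 45.5% were 21 nt and 48.2% were 22 nt. For 20 other conserved and legume miRNAs with their listed sequence as the main form in this library, the share plus T had a median of 0.588% and a largest value of 9.60%, for miR156. Whether T is encoded after these could not be checked, since no legume genome was used here. The level of miR1510-3p was 695 RPM (680.2 to 710.1).

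Mung bean held little miR1510-3p, and in another frame. Of 205 like reads, 81.5% were 22 nt (75.6 to 86.2) and 85.9% began 2 bases downstream of the pigeon pea start. The main form TTGTTTTACCTATTCCACCAAT had 164 reads and differed from the transgene's form at that start by C20A, counted from 1 at its 5' end. It was followed by 1 more T in 1 of 168 reads, or 0.595% (0.105 to 3.29). The main form itself ends in T, and the form without that T had 2 reads. Without a mung bean genome, an added T cannot be separated from an encoded one at either position. The 21-nt form of the pigeon pea frame had 2 reads. The level of the main form, with its 3' variants, was 4.32 RPM (3.69 to 5.03). Of 20 other miRNAs in this library, the share plus T had a median of 0.643% and a largest value of 5.38%, again for miR156.

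Endogenous Arabidopsis miRNAs were measured in the same way, for comparison with miR1510. Of 12 miRNAs without a T next to the mature sequence in the genome, 7 had a lower monouridylated share in heso1-1 than in Col-0, 2 a higher one and 3 did not pass (Fisher's exact test per miRNA, Benjamini-Hochberg adjusted over 12). miR319a, which targets TCP transcription factors (MIR319a, chromosome 4, 12353109 to 12353129, plus strand), was at 25.2% in Col-0, 20.01% in urt1-1 and 2.18% in heso1-1. miR156, which targets SPL transcription factors, was at 24.6%, 5.51% and 1.52%, and miR158a at 5.39%, 2.07% and 0.608%. For miR158a the direction of heso1-1 against Col-0 turned when T added after a trimmed end was counted too, with any added T at 24.4% in Col-0 and 35.6% in heso1-1. The median share over the 12 was 2.80% in Col-0, 1.84% in urt1-1 and 0.633% in heso1-1. The median difference was -1.24 points for heso1-1 against Col-0, -1.95 with at least 1000 reads per library and -0.715 with any added T, trimmed ends included. As a ratio of shares, heso1-1 to Col-0, miR1510-3p was at 0.0420, near miR396a at 0.0588, miR156 at 0.0615 and miR319a at 0.0862.

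Between the 2 mutants, whose files share a format, 7 of the 12 were lower in heso1-1 than in urt1-1 and 2 were higher, with a median difference of -0.890 points. With any added T, trimmed ends included, 5 were lower and 3 higher with a median of -0.331, and miR158a turned direction, at 35.6% in heso1-1 and 9.93% in urt1-1. With miRNAs followed by a genomic T included, 11 were lower and the median was -0.584. The lower ones included miR319a (difference -17.8 points, adjusted p = 7.81e-91 by Fisher's exact test) and miR162, which targets DICER-LIKE 1, at 0.512% against 3.60%. The higher ones were miR825, at 25.3% of 170 reads in heso1-1 against 1.72% of 116 in urt1-1 and 11.4% of 140 in Col-0, and miR159b, at 2.93% against 2.40%. miR825 was no longer called higher than Col-0 when any number of added T was counted. Reads of miR159b cannot be separated with certainty from its near copy miR159a.

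Against Col-0, urt1-1 had 7 lower, 2 higher and 3 that did not pass, with a median difference of -0.652 points. The median was -1.53 with at least 20 reads per library and -1.23 with any added T, trimmed ends included. miR156 differed the most (difference -19.1 points, adjusted p = 1.21e-91 by Fisher's exact test), and miR162 was higher, at 3.60% against 1.40%. The miR1510 difference of 1.44 points lay above 91.7% of the 12 endogenous differences. In comparisons against Col-0 the file format differed too, and its part cannot be separated from genotype.

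**Figure D2:**
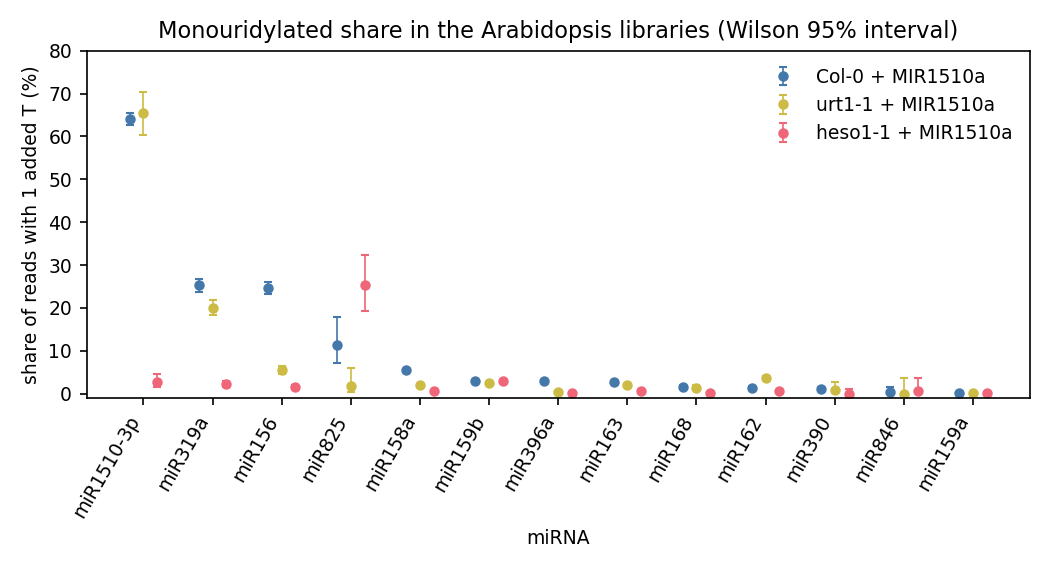
Share of anchored reads with 1 added T (vertical axis, %) for miR1510-3p and 12 endogenous miRNAs (horizontal axis) in the 3 Arabidopsis libraries, 1 point per library with its Wilson 95% interval. miR1510-3p, miR319a and miR156 were at 2.69%, 2.18% and 1.52% in heso1-1, while miR825 was at 25.3% there.

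Levels of endogenous miRNAs differed widely between Col-0 and both mutants. Of 36 miRNAs, 5 were at least 2-fold higher and 20 at least 2-fold lower in heso1-1, and 6 were higher and 15 lower in urt1-1. Scaling by the median ratio, which was 0.457 for heso1-1 and 0.794 for urt1-1, gave 11 higher and 13 lower, and 10 higher and 14 lower. Of 13 miRNAs on the Arabidopsis list, 8 were lower in heso1-1 and 6 in urt1-1, and of 24 conserved ones 12 and 9. miR159, with both copies together, is in both lists. miR393, which targets auxin receptor genes, was at 103 RPM in Col-0, 6.08 in urt1-1 and 3.81 in heso1-1. miR161.2, which targets PPR genes, was at 191, 5.53 and 5.96. miR166, which targets HD-ZIP III genes, was the most abundant at 12477, 9950.4 and 5842 RPM. miR162 was higher in both mutants, by 3.65-fold (3.54 to 3.77) in urt1-1 and 2.54-fold (2.46 to 2.62) in heso1-1.

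Nutrient-responsive miRNAs went both ways. Of 6 measured, 4 were higher and 2 lower in each mutant library than in Col-0. Of the 2 measured miRNAs on the 22-nt list, miR393 was lower and miR173 did not pass, in both. The copper-responsive miR398 (both copies together) was at 0.177 RPM in Col-0, 8.74 in urt1-1 and 7.11 in heso1-1, and miR408 at 0.0253 (1 read), 8.06 and 4.52. The sulfate-responsive miR395a was at 0.608, 35.3 and 4.37. The phosphate-responsive miR399b was at 5.63, 0.956 and 0.296, and miR827 at 3.24, 0.820 and 0.185. Between the mutants, 3 of 28 miRNAs passed: miR395a (ratio of heso1-1 to urt1-1 0.124), miR395b (0.237) and miR172a (0.328) were lower in heso1-1 and 0 were higher. Over the 28 miRNAs with enough reads in every comparison, the SD of the log2 ratio was 0.65 between the mutants, against 2.57 and 2.82 for heso1-1 and urt1-1 against Col-0. The read minimum leaves out of these 28 several miRNAs that were low in both mutants.

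Trans-acting siRNAs, made from TAS transcripts after cleavage by a miRNA, followed the same division. TAS1-siR480 was at 859.8 RPM in Col-0, 5.67 in urt1-1 and 2.44 in heso1-1, that is 152-fold (122 to 190.4) and 352-fold (276 to 455) lower. TAS1-siR255 was 3.31-fold and 6.97-fold lower. TAS1C as a whole (AT2G39675, chromosome 2, 16537288 to 16538277, minus strand) had 1874 RPM in Col-0, 606 in urt1-1 and 292 in heso1-1. Of these, 21-nt reads of siR480 alone gave 827, 4.92 and 1.89. The neighbouring TAS2 (AT2G39681, 16539384 to 16540417, minus strand) had 1007, 484 and 259.8. TAS1B differed from TAS1C and TAS2, at 98.2 in Col-0, 155 in urt1-1 and 31.2 in heso1-1. TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437, plus strand) was higher in the mutants, at 259.96, 749 and 451. TAS3b (AT5G49615) was at 11.0, 22.0 and 11.3, so heso1-1 was near Col-0 there. The siRNA tasiARF, which matches both loci and targets auxin response factors, was at 9.99, 25.003 and 16.1. miR173, which triggers TAS1 and TAS2 siRNAs, was at 2.56, 4.58 and 2.85 RPM. Within TAS3, 12 abundant 21-nt siRNAs had log2 ratios to Col-0 with an SD of 1.49 in urt1-1 and 1.56 in heso1-1, and of 0.18 between the mutants.

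**Figure D3:**
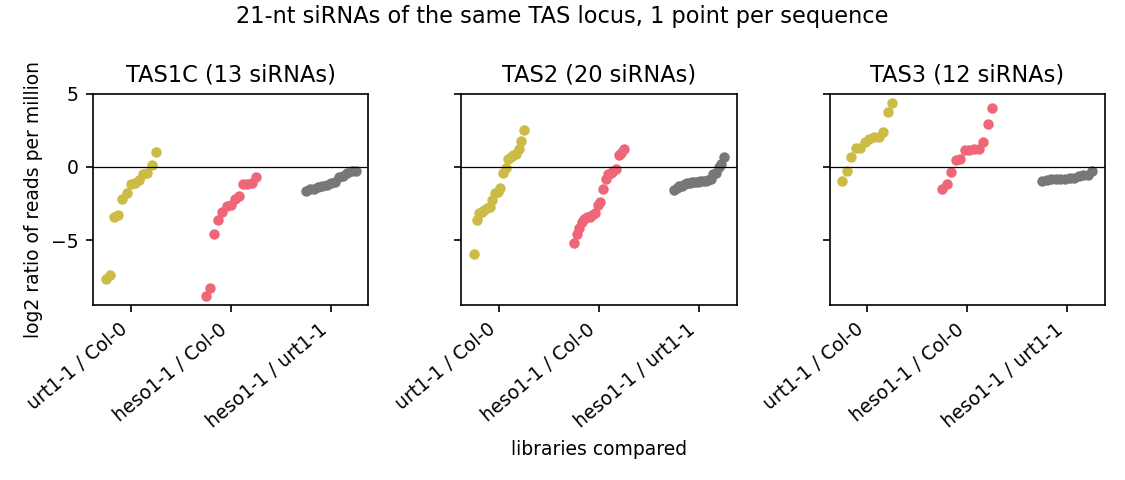
Log2 ratio of RPM between 2 libraries (vertical axis) for abundant 21-nt siRNAs of TAS1C, TAS2 and TAS3 (panels), 1 point per sequence, for the 3 pairs of libraries on the horizontal axis. The SD between the mutants was 0.49, 0.57 and 0.18 for the 3 loci, against 2.60, 1.98 and 1.56 for heso1-1 against Col-0.

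The mung bean and pigeon pea libraries differed in the miRNAs that legumes are known for. Growth temperature and file format differed between these 2 libraries too and cannot be separated from species. In mung bean, 8.91% of reads were under 18 nt and counted in the total. Of 30 listed miRNAs, 6 were at least 2-fold higher and 17 lower in mung bean. Among 6 miRNAs on the legume list, 4 were lower. They were miR1507a (26487 RPM in pigeon pea, 2276 in mung bean), miR1511 (9711 and 685), miR2118a (1183 and 17.8) and miR482b (231 and 9.99). miR2118 and miR482 target NB-LRR resistance genes. miR1514a (20.3 and 86.1) and miR1515a (1.498 and 18.8) were higher in mung bean. miR166 (72511 and 14770.1) and miR160 (187.5 and 6.74) were lower there, and miR159, with both copies together, was higher (5262 and 16206). Relative to the sum of listed miRNAs, the split was 10 higher and 7 lower, and after scaling by the median ratio of 0.441 it was 8 higher and 10 lower. Of 24 conserved miRNAs, 4 were higher and 13 lower, of 5 on the 22-nt list 1 and 3, and of 5 on the nutrient list 0 and 1 (miR2111). The miR2111 ratio of 0.448 turned direction relative to the sum of listed miRNAs (1.42) and after scaling by the median ratio (1.02). The anchor can miss reads of a family whose sequence differs between species.

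Few reads in the libraries matched miRNAs listed for the other plants. Of 20 Arabidopsis-lineage families, 3 had a read in pigeon pea and 1 in mung bean, with 39 reads (3.24 RPM) and 6 reads (0.154 RPM) in all. Of 10 families on the legume list, only miR1511 had reads in the Arabidopsis libraries, with 1 in Col-0, 2 in urt1-1 and 8 in heso1-1. miR1507a, which was more abundant than miR1511 in pigeon pea, had 0 reads in each of them. The origin of the miR1511 reads was not tested.

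The size profile of the reads differed between the libraries. Of reads of 18 to 28 nt, 24-nt reads made up 31.1% in pigeon pea, 13.3% in mung bean, 11.1% in Col-0, 13.9% in urt1-1 and 11.2% in heso1-1. The 21-nt class was at 19.8%, 14.9%, 12.2%, 13.2% and 12.03%, and the 22-nt class was the largest in mung bean at 19.2%. The 23-nt class was at 5.58%, 9.08%, 8.99%, 10.4% and 10.03%. Reads that matched the chloroplast genome made up 34.6% in Col-0, 34.02% in urt1-1 and 35.2% in heso1-1, and nuclear ribosomal RNA 13.1%, 14.1% and 16.2%. Ribosomal RNA of the organelles was counted with their genomes.

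**Figure D4:**
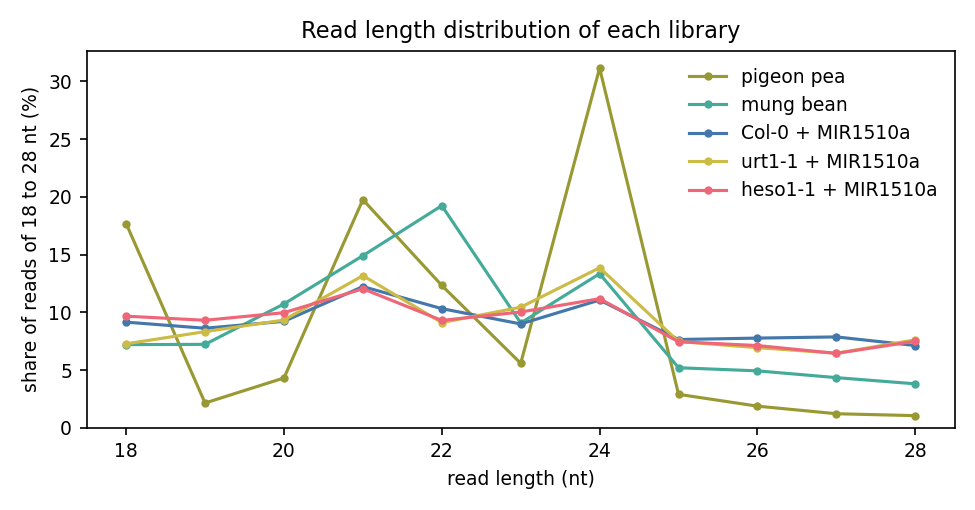
Share of reads of 18 to 28 nt (vertical axis, %) by read length in nt (horizontal axis), 1 line per library. The 24-nt class reached 31.1% in pigeon pea and 11.1% to 13.9% in the other libraries.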

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

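The tests of explanations in this part were chosen after the results were seen, while the comparisons of miR1510 shares and of endogenous shares against Col-0 that some of them read were fixed before. For longer reads, the miRNAs were parted after their values were seen, and the verdict on them as 1 set had changed with a bound on the spread added later. The bound on the spread for miR173 was also added after its value was seen.

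A signal outside the main measurement was the soybean form of miR1510-5p in the mung bean library, with 24 reads, above the limit that a count of 0 allows. Carry-over from the Arabidopsis libraries at the rate of miR158a would give 0.549 reads (0.201 to 1.19). Whether mung bean encodes this sequence was not tested.

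The miR1510 share plus T was low in heso1-1. A base left over from the adapter was excluded, because the median endogenous share in urt1-1 was 1.84% while miR1510 stood at 65.5% there. The different making of the Col-0 file was excluded as the whole cause, because heso1-1 differed from urt1-1, of the same format, by -62.8 points. The heso1-1 genotype stays open as a hypothesis: the median endogenous difference from urt1-1 was -0.890 points, and -0.331 with any added T, trimmed ends included, but 1 library per genotype does not separate genotype from library.

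Levels of miRNAs and siRNAs stood far apart between Col-0 and both mutants. Sequence-dependent capture that differs between the Col-0 library and the mutant libraries had the values it needs among TAS3 siRNAs. These siRNAs of the same locus had log2 ratios to Col-0 with an SD of at least 1.49, against 0.18 between the mutants. That test held 12 siRNAs and no miRNA, so it does not decide the cause of the miRNA differences. Less miR173 as the reason for fewer TAS1 and TAS2 siRNAs stays open: its ratio to Col-0 was 1.79 (1.29 to 2.46) in urt1-1, above 0.5 by more than the TAS3 spread, but 1.11 (0.817 to 1.51) in heso1-1, which is not. The loss of either transferase stays open, with an SD over miRNAs of 0.65 between the mutants and no second library of any genotype.

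Endogenous shares plus T were lower in both mutants than in Col-0 for miR156, miR158a, miR163, miR319a and miR396a, although any added T on miR158a, trimmed ends included, was higher in heso1-1. Lower recovery of all longer reads would lower reads with any further base alike, added or encoded. For miR156, miR158a and miR396a, reads with 1 further base other than T stood, relative to Col-0, at least 5.49-fold above reads plus T in urt1-1. In heso1-1 they stood at least 13.9-fold above. Many of these bases can be encoded. In urt1-1 the genomic next base made up 164 of 198 such reads for miR156 (A). It made up 68 of 76 for miR396a (C) and 144 of 488 for miR158a (A). The fold values argue against lower recovery as the whole cause for these miRNAs, which were picked after their values were seen. The named miRNAs as 1 set gave no verdict. For miR163 and miR319a lower recovery stays open, since miR163 had a ratio of 0.711 (0.548 to 0.924) in urt1-1 but 1.95 (1.35 to 2.86) in heso1-1, and miR319a, at 0.486 (0.0877 to 1.82) in urt1-1, had 0 reads with another base in heso1-1. The share plus T was also not lower everywhere in urt1-1, with miR162 at 3.60% against 1.40% in Col-0. The loss of either transferase stays open, with a median difference of -0.652 points between urt1-1 and Col-0 (-1.53 to -0.521 over the alternatives) and 1 library per genotype.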

How the results depend on the processing

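The alternative 5' frames, reads over 24 nt left out, the comparison of the 2 mutants for endogenous miRNAs, and for those miRNAs the genomic T and trimmed ends were chosen after seeing the data. No paired analysis was possible because each group was 1 library. Of the values that answer a comparison, 110 stayed within their bounds, 53 moved, 4 reversed and 1 lost its call. Of single ratios 403 stayed, 293 moved and 8 reversed. Of those that stayed, 130 came from the minimum of 20 reads and 68 from that of 1000. A read minimum leaves a ratio as it is, so these could not move. Depth limits miR1510 in the mutants, with 351 reads in urt1-1 and 483 in heso1-1. For every value below, the cause was not tested.

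The miR1510 differences kept direction and call under every alternative except the other 5' frames. In the frame listed before the data were examined, they were 7.13 points for heso1-1 against Col-0 (Fisher's exact p = 0.326), -1.96 for urt1-1 against Col-0 (p = 1) and 9.09 for heso1-1 against urt1-1 (p = 1), on 51, 2 and 11 reads in Col-0, urt1-1 and heso1-1. In the frame 2 bases downstream they were -5.60 (Fisher's exact p = 0.000612), -5.17 (p = 0.0570) and -0.426 (p = 1). There the next encoded base was not known. In mung bean, the share of 22-nt like reads was 94.9% with at most 1 mismatch and 90.6% without sequences of fewer than 3 reads.

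Scaled by the median ratio, heso1-1 against Col-0 had 11 higher and 13 lower, urt1-1 against Col-0 10 higher, and mung bean against pigeon pea 10 lower. With at least 1000 reads, heso1-1 against Col-0 had 1 higher and 9 lower, urt1-1 against Col-0 1 and 6, heso1-1 against urt1-1 0 lower, and mung bean 11 lower; here fewer miRNAs were tested. With at least 20 reads, heso1-1 against urt1-1 had 5 lower. Relative to the sum of listed miRNAs, mung bean had 10 higher and 7 lower. Single ratios that reversed were, scaled by the median, miR166 at 1.02 and miR822 at 1.003 (heso1-1 against Col-0) and miR390 at 1.07 and miR2111 at 1.02 (mung bean), and relative to the sum, miR171b at 1.37, miR390 at 1.49, miR394 at 1.27 and miR2111 at 1.42 (mung bean).

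Per 1000000 reads of 20 to 24 nt, miR1510-3p was at 1049.8 in pigeon pea, 7.39 in mung bean, 213 in Col-0, 57.5 in urt1-1 and 43.5 in heso1-1. Per 1000000 reads of conserved miRNAs it was at 8294, 122.5, 4893, 1021 and 1225.

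With distinct sequences counted once, the 21-nt class was at 7.82% in pigeon pea, 7.81% in mung bean, 9.25% in Col-0, 10.3% in urt1-1 and 9.26% in heso1-1, and the 24-nt class at 60.6%, 47.9%, 22.2%, 27.6% and 23.0%. Without sequences seen once, the 21-nt class was at 22.6%, 15.5%, 12.4%, 13.4% and 12.2%, and the 24-nt class at 24.4%, 10.4%, 10.36%, 12.8% and 10.6%.

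For endogenous shares plus T, at least 1000 reads left 1 higher in heso1-1 against Col-0 and 1 against urt1-1. Any number of T gave 0 higher in heso1-1 and 1 in urt1-1 against Col-0, and any added T, also after a trimmed end, gave 1 and 1 against Col-0, and 5 lower and 3 higher in heso1-1 against urt1-1. The median differences kept their sign, from -1.95 to -0.715 points for heso1-1 against Col-0, -1.53 to -0.521 for urt1-1 against Col-0 and -1.30 to -0.331 for heso1-1 against urt1-1. With miRNAs that have a genomic T next to them, 11 were lower in heso1-1 against Col-0 and 11 against urt1-1.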

Other observations

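The values in this part were picked after the data were seen. miR158a, a miRNA of the Arabidopsis lineage (MIR158a, AT3G10745, chromosome 3, 3366349 to 3366368, minus strand), differed at trimmed 3' ends. Reads 1 base shorter than the mature sequence with an added T made up 5.53% in Col-0, 1.99% in urt1-1 and 25.6% in heso1-1. The whole mature sequence made up 67.7%, 67.9% and 41.1%. Shorter reads with no added base were at 3.39%, 16.7% and 18.6%. Reads of miR158a with any added T were thus most frequent in heso1-1, at 35.6%, against 24.4% in Col-0 and 9.93% in urt1-1, while the whole sequence plus 1 T was least frequent there. miR825 (MIR825, AT2G26211, chromosome 2) carried 2 or more T in 15.7% of reads in Col-0, 2.59% in urt1-1 and 10.6% in heso1-1.

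Some endogenous miRNAs have a T next to the mature sequence at a genomic copy, so an added T cannot be separated from an encoded one. Their shares plus T were 27.9% in Col-0, 18.4% in urt1-1 and 4.48% in heso1-1 for miR157. For miR403, which targets AGO2, they were 17.2%, 2.47% and 0.151%, and for miR161.1 4.51%, 3.39% and 0.173%. The other 5 had shares below 2%: miR165 0.393%, 0.322% and 0.194%, miR166 0.136%, 0.163% and 0.164%, miR396b 1.02%, 1.24% and 0.820%, miR395b 0 of 130 reads, 0.471% and 0.538%, and miR167a 0.0205%, 0 of 2742 reads and 0.0263%. The pigeon pea form of miR1510-5p, AGGGATAGGTAAAACAACGAC, differed from the transgene's by T18C, counted from 1 at its 5' end, and had 45 reads in pigeon pea. It also had 19 reads in Col-0, 2 in urt1-1 and 4 in heso1-1.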
